A study of Rattus norvegicus with 58 samples.

How the data were processed

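RNA from the medial layer of the thoracic and abdominal aorta of 29 rats was measured on 58 Agilent rat oligonucleotide arrays of 20500 probes, controls not counted. Per the labels, RNA was extracted with the Qiagen RNeasy kit and labelled with a fluorescent linear amplification kit from Agilent. Each rat was hybridized on 2 arrays, once in Cy5 and once in Cy3, with a reference in the other dye, made by pooling WKY control RNA from 6 rats. The groups were 6 WKY controls, 6 WKY given angiotensin, 6 SHR controls, 6 SHR given nifedipine for 2 weeks, and 5 SHR given nifedipine for 2 weeks and then kept for 3 weeks without it. Replicate numbers are those of the labels.

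The submitters' processing notes name Agilent Feature Extraction 7.1 for spot quantification. Per the file headers, the deposited scanner files hold the mean spot and median local background intensity of each channel, not background-subtracted. They also hold the authors' log10 ratio of red over green after Feature Extraction background subtraction and dye normalization, per the file headers. Other columns are, per the file headers, 0 or 1 flags set by Feature Extraction for spots well above background, saturated or unlike their neighbours. The deposited value table holds the authors' log2 ratio of sample over reference, with the sign already turned for dye. How that table was normalized is not given in the sources used here; its columns were set against a loess fit of the background-subtracted signals and correlated with it at 0.999 to 1.000. Its column medians lay between -0.019 and 0.021. The median absolute deviation was 0.262 to 0.271 on the washout arrays and 0.216 to 0.222 on the others, so the washout arrays are scaled to another spread, and the table served only as an alternative.

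From the scanner files, background was corrected with normexp (offset 50), log2 ratios were normalized within arrays by loess, and both arrays of a rat were averaged after turning the sign of the Cy3 arrays (limma 3.58.1 in R 4.3.3). Spots marked as outliers on either array were left out for that rat (0.479% of values). Probes were given symbols by RefSeq accession (3757) or by a symbol in their description, traced through a retired accession (79); 16664 probes have none and appear only in counts. Where probes shared a symbol the brightest was kept. A probe had to be well above background in the sample channel on both arrays of at least 3 rats of a group, which 19556 of the 20500 passed, and needed at least 3 values per group, which removed 4; 19447 were tested. The share of probes well above background ran from 79.4% to 98.0% over arrays, and the median sample signal from 112.9 to 283.8. No array had over 16 saturated sample spots.

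One limma model with the 5 groups was fitted to all 29 rats, with empirical Bayes moderation and adjusted p values by Benjamini and Hochberg within each of 5 comparisons: SHR control against WKY control, WKY angiotensin against WKY control, SHR nifedipine against SHR control, SHR washout against SHR control, and SHR washout against SHR nifedipine. The threshold was an adjusted p of 0.05. Of 27 gene lists fixed beforehand, 26 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with an estimated correlation as the alternative. List members were counted over all genes and after adjustment over the list alone. The animals differ in spread over probes: the standard deviation of a rat's log2 ratios was 0.077 to 0.098 in WKY controls and 0.134 to 0.168 with angiotensin. It was 0.198 to 0.397 in the SHR control and nifedipine groups and 0.224 to 0.279 after washout. As these are ratios to a WKY pool, it also grows with distance from WKY. Between 2 rats of a group, the root mean square log2 difference was 0.098 to 0.153 in WKY controls and 0.104 to 0.174 with angiotensin. It was 0.111 to 0.358 in SHR controls, 0.113 to 0.357 with nifedipine and 0.132 to 0.241 after washout. The model shares its variance over groups. The angiotensin comparison is thus tested with a wider error than its own animals show, and the comparisons within SHR with a narrower error.

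Named genes follow a rule fixed before the data were read. Among genes past the threshold with no overlap between the groups' animals they are the 10 largest rises and 10 largest falls of each comparison; the 5 smallest p values where fewer than 6 pass; up to 4 members past the threshold, by size, of each list that camera called or that held at least 3; and Cd36, Ace, Agtr1a, Fn1 and Spp1 throughout. Some genes that the rule selects are not used here. Further fixed genes, Cacna1c, Acta2, Myh11 and Col1a1, have no named probe. Adipoq and Fabp4 and, in some paragraphs, members of a called list were named outside the rule, after their values were seen.

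The gene and list tests were checked on simulated animals with the moderated spread of each gene and 200 genes changed by known sizes. Values were drawn from normal distributions, with the same spread in all groups and no correlation between genes. The real groups differ in spread and list members are correlated, so the rates below hold for that simpler setting only. Changes of 0.5 on the log2 scale were recovered in 83.6% to 92.5% of cases, of 1 in 95.5% to 100%, and of 2 in 100%, with none in the wrong direction; 2.09% to 5.88% of calls were false. A list shifted by 0.3 was called in all 5 comparisons, and no other list was.

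Fixed alternatives were the Feature Extraction log ratio, no background subtraction, median centring, scaling between arrays, no or a strict filter on dim probes, each probe alone, each dye alone, only the 2 groups compared, an intensity trend, array weights, all 58 arrays with a dye term and the rat as a random block, the replicate number as a block, the authors' value table, a fold of at least 1.5 as well, and leaving out each animal in turn. Scaling between arrays acts on mean intensity and leaves ratios as they are, so it cannot move a result. A block by scan date was not used here, as the files give none. Chosen after the data were seen were fits without SHR control 1, SHR control 4 and SHR nifedipine 1, the rats of widest spread; with the mean of the adipocyte markers as a covariate; and without WKY controls 5 and 6. Correlations between comparisons that share animals were set beside 100 simulated data sets without group effects and 20 splits of the shared group.

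Single animals far from their group were sought by Dixon's ratio, the gap to the nearest animal over the range, among named genes, called lists and the spread over probes, at a limit passed by 5% of normal samples in 200000 simulations. Group labels were split in 100 ways per comparison, the real split included. The outcomes that would speak for or against each explanation were worded before the tests were run unless said otherwise, but through a saving error their table was stored only after the tests had finished, with the wording unchanged. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.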

Results

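Gene expression in the medial layer of the aorta was compared between normotensive WKY rats and spontaneously hypertensive SHR rats, and between treated and untreated rats of each strain. Angiotensin is a hormone that raises blood pressure, and nifedipine is a blocker of L-type calcium channels that lowers it. Of 29 rats, 6 were WKY controls, 6 WKY given angiotensin, 6 SHR controls, 6 SHR given nifedipine for 2 weeks and 5 SHR studied after 3 further weeks without the drug. Values are log2 ratios to a pool of WKY control RNA, averaged over 2 arrays of opposite dye per rat, and differences are given as log2 with the standard error (SE). Each of 19447 genes or unnamed probes was tested with limma; 3551 of these carry a gene symbol. A change means an adjusted p under 0.05 over all tested genes, and gene lists were tested with camera.

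The aortic media of untreated SHR rats differed from that of untreated WKY rats in many genes. Igfbp2, a binding protein of insulin-like growth factors, changed by -2.11 (SE 0.15, adjusted p = 8.2e-11), and all 6 SHR controls lay below all 6 WKY controls. Rgs5, a brake on receptor signalling in vascular smooth muscle, changed by -1.51 (SE 0.11), and Pik3r1, the regulatory subunit of a lipid kinase, by -1.49 (SE 0.08), again with no overlap between the groups. Cd36, the fatty acid transporter known to be defective in SHR, changed by -1.38 (SE 0.12). Fn1, which encodes fibronectin, was lower by a log2 difference of -1.08 (SE 0.08). limma called 6001 genes changed, 30.9% of those tested, with 2971 higher and 3030 lower (2529 and 1766 with median centring); 533 of them differed by at least 1.5-fold. At an unadjusted p under 0.05 there were 8005. No overlap between the 6 and 6 animals was seen in 2824 genes, which is 14.5% where chance gives 0.216%.

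Other genes with large rises and no overlap were Dbp (1.62), a clock output gene, the growth regulator Plagl1 (1.61), the peptide transporter Slc15a3 (1.37), Dlk1 (1.28), Mafg (1.21), Prps2 (1.18) and Tcea2 (1.15). Nr4a3 rose by 2.17 on its brightest probe, while another probe for it read 0.14, and the other Plagl1 probe read 0.42. Large falls were those of the secreted phospholipase Pla2g2a (-1.63), Dmbt1 (-1.30), Ckm (-1.28), Lgals3 (-1.11) and the desaturase Scd2 (-1.06). Among the fixed genes of interest Ace (0.02) and Agtr1a (0.06) did not pass, with adjusted p of 0.872 and 0.289. Spp1, which encodes osteopontin, rose by 0.45 (SE 0.16, adjusted p = 0.037).

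By gene group, cholesterol synthesis was lower in SHR: of 15 tested members 10 fell and none rose (11 fell when adjusted over the list alone), among them Hmgcs1 (-0.65), Msmo1 (-0.34), Sqle (-0.34) and Sc5d (-0.33). The mean difference of that list was -0.23, with camera adjusted p = 0.000404 and all 6 SHR controls below all WKY controls; adjusted p = 0.45 with an estimated correlation. Heat shock and unfolded protein response genes were higher, 9 of 18 rising and none falling, adjusted over all genes or over the list alone, with a mean of 0.39, camera adjusted p = 0.00126 and 5 of 6 animals above all WKY controls; adjusted p = 0.45 with an estimated correlation. Hspa1a rose by 2.21, Hspa8 by 1.01, Dnaja1 by 0.79 and Herpud1 by 0.67. SHR control 1 stands apart in these genes: its Hspa8 value was -0.19, against 1.11 to 1.57 in the other SHR controls, and its Dnaja1 value -0.60 against 0.79 to 1.48. Endothelial markers were lower, with 3 of 5 falling and none rising: Erg (-0.80), Cd93 (-0.61) and Plvap (-0.54), mean -0.43, camera adjusted p = 0.030; adjusted p = 0.45 with an estimated correlation. WKY controls 5 and 6 stand apart in that list, at 0.17 and 0.19 against -0.12 to -0.038 in the other WKY controls, and without them its mean was -0.34 and it was not called (adjusted p = 0.0889). Ribosomal protein genes were lower as a list, 13 of 37 falling and 1, Rpsa (0.41), rising, with a mean of -0.11 and camera adjusted p = 0.00126; adjusted p = 0.45 with an estimated correlation.

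Lists that camera did not call also held changed members, as did the array at large, where 30.9% of tested genes were called. The counts below are to be read against that share. Ion channel genes went both ways, 7 of 34 higher and 5 lower: Trpc4 (0.94) and Kcnmb1 (0.66), a subunit of the calcium-activated potassium channel, rose, while Kcnj8 (-0.59) fell. Of 48 vasoactive genes 6 rose, among them Ednra (0.54) and Nos2 (0.77), and 10 fell, among them Gucy1b1 (-0.53). Growth factor and TGF-beta genes went both ways, 6 of 31 higher, such as Smad7 (1.03) and Tgfb3 (0.80), and 7 lower, Igfbp2 most of all. Of 26 immediate early genes 10 were higher, such as Egr1 (1.20), and 4 lower, such as Jun (-0.91) and Klf6 (-0.77), with camera adjusted p = 0.0712. Redox enzymes fell in 10 of 39 and rose in 5: Gpx4 (-0.55), Prdx6 (-0.45), Gstm5 (-0.57) and Gsta1 (-0.80). The Gsta1 difference rests on SHR control 1, at -2.16 against -0.69 to -0.19 in the other SHR controls measured, and without it was -0.46 (adjusted p = 0.137). Contractile genes rose in 3 of 10, Kcnmb1, Cnn1 (0.45) and Cald1 (0.12). The fat genes Ucp1 (1.94), Thrsp (1.12), Fasn (1.09) and Cpt1b (1.17) were higher, whereas Adipoq differed by -0.15 and Fabp4 by 0.05, neither passing. As lists, adipocyte markers had 5 of 17 members higher and none lower (mean 0.35, camera adjusted p = 0.0517) and fatty acid oxidation genes 5 of 28 higher and 3 lower (mean 0.10, camera adjusted p = 0.372). The markers of striated muscle Ckm, Myl11 (-1.32) and Myh6 (-0.69) were lower in SHR; their list mean was 0.66 in WKY control 5 and 0.85 in WKY control 6, against -0.44 to -0.22 in the other WKY controls, and without these 2 rats Myl11 (-0.18) and Myh6 (-0.054) did not pass. Nor did Sqle (-0.20) and Cald1 (0.058) without the 3 animals of widest spread. Without SHR control 1, SHR control 4 and the third animal of widest spread, SHR nifedipine 1, 5549 genes were called, and without WKY controls 5 and 6, 4845.

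**Figure D1:**
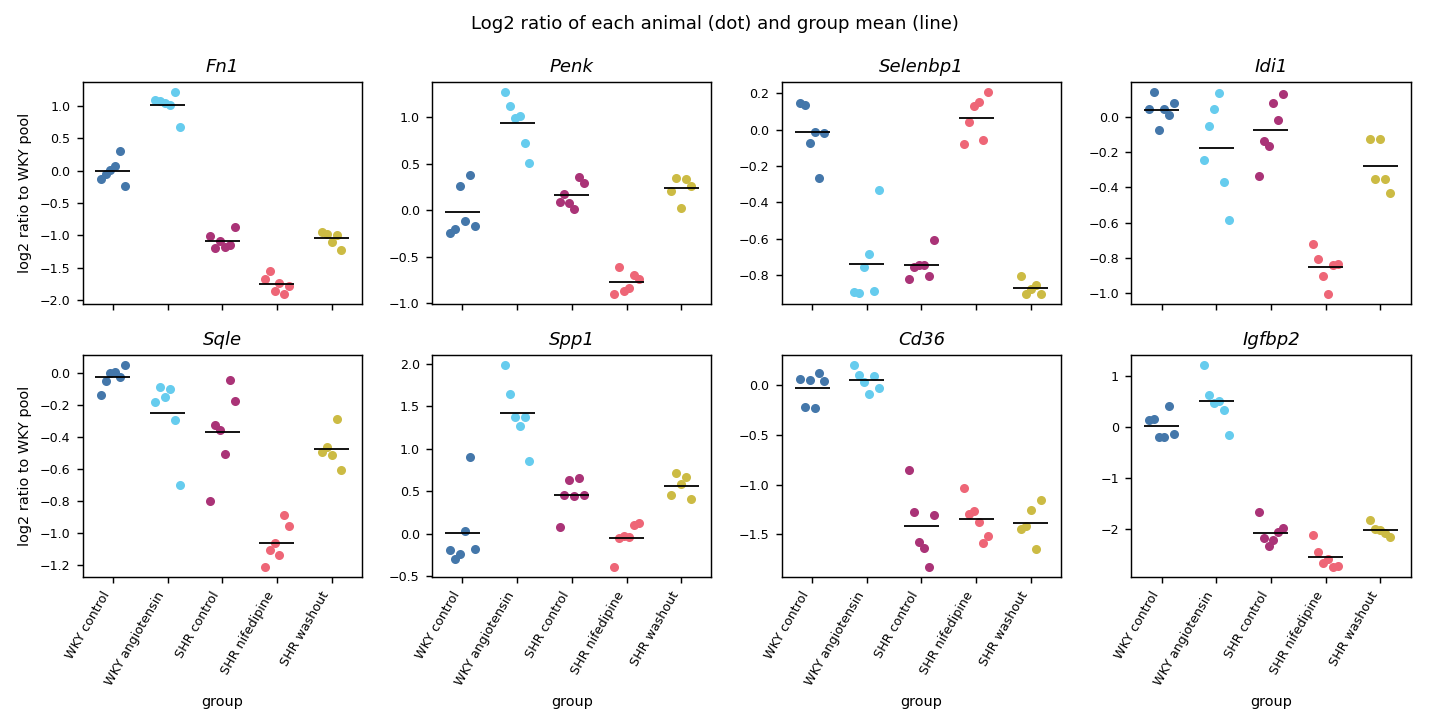
Log2 ratio to the WKY pool of 8 named genes in each rat (dots) with group means (lines), for the 5 groups.

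Angiotensin in WKY rats raised genes of the extracellular matrix. Fibronectin (Fn1) rose by 1.03 (SE 0.08, adjusted p = 1.1e-08), osteopontin (Spp1) by 1.41 (SE 0.16) and Ltbp2, which binds elastic fibres, by 1.10 (SE 0.13), in 6 treated against 6 control rats. Esm1, an endothelial proteoglycan, rose by 1.38 (SE 0.12, adjusted p = 4.6e-08), and the opioid-like peptide precursors Pnoc and Penk by 1.33 (SE 0.17) and 0.95 (SE 0.11). Except for Spp1, no animal of either group overlapped the other group in these genes. limma called 635 genes changed, 351 higher and 284 lower (227 and 50 with median centring, 1003 and 1065 with only the 2 groups); 70 differed by at least 1.5-fold, and 2843 had an unadjusted p under 0.05. No overlap between the animals was seen in 1026 genes, 5.28% where chance gives 0.216%. The count moved with the fit: 2068 when only the 2 groups compared were fitted, 2180 with array weights, 1215 on all 58 arrays, 1803 from the authors' value table and 277 with median centring.

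Further rises were those of the clock genes Dbp (1.14) and Bhlhe41 (0.86), the leukocyte adhesion molecule Vcam1 (0.92) and the transcription factor Runx1 (0.88). Cthrc1 (0.73), Hsd11b1 (0.76) and Timp2 (0.41) rose as well. Among genes without overlap the largest falls were in Selenbp1 (-0.73, SE 0.08), Tsc22d1 (-0.72), Rgs5 (-0.64), the glycolytic Aldoc (-0.64), the cation transporter Slc22a3 (-0.62), Ppp1r1a (-0.57), Unc119 (-0.55), the smooth muscle actin Actg2 (-0.53), Gnao1 (-0.51) and Fads1 (-0.50). The guanylate cyclase subunit Gucy1a1 fell (-0.74), and so did the vasopressin receptor Avpr1a (-0.32). In calcium handling, Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell (-0.38) while its inhibitor Pln rose (0.38) and the channel subunit Cacna1d rose (0.23). Ace (-0.04), Agtr1a (0.04) and Cd36 (0.08) did not pass.

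Matrix lists rose together. Proteoglycans and matricellular proteins had 5 of 22 members higher and 1 lower (8 and 2 when adjusted over the list alone), with a mean of 0.19 and camera adjusted p = 0.000358; this held with an estimated correlation (adjusted p = 0.00289). Collagens and elastic fibres had 2 of 11 higher and none lower (3 when adjusted over the list alone), Ltbp2 and Pcolce (0.55). The mean was 0.23, with camera adjusted p = 0.000362 and 6 of 6 treated rats above all controls. With an estimated correlation the camera adjusted p was 0.048. The median member moved by 0.077, so a few members carry this mean. The 11 tested members are a part of the 43 genes in the list. Proteases and their inhibitors had 3 of 19 higher and 1 lower (6 and 1 over the list alone), among them Ctsb (0.21) and, lower, Mmp16 (-0.39). For this list camera adjusted p = 0.0095, and adjusted p = 0.122 with an estimated correlation. Its median member moved by 0.048 (mean 0.13) and that of the proteoglycans by 0.054, so a few members carry these means as well. The tested members were 19 of 34 and 22 of 40 genes. Circadian genes rose in 3 of 8 (mean 0.25, camera adjusted p = 0.00559), proliferation genes in 2 of 9, Stmn1 (0.40) and Cdk1 (0.28), with camera adjusted p = 0.020, and leukocyte markers in none singly (mean 0.086, camera adjusted p = 0.035). With an estimated correlation these gave adjusted p = 0.158, 0.158 and 0.311. The circadian list mean also lay above the WKY controls in SHR controls (0.40), nifedipine rats (0.53) and washout rats (0.54). Whether these genes were low in the WKY controls, for example through the time of tissue collection, was not tested.

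Lists that fell were contractile smooth muscle, in 3 of 10 members (Actg2, Csrp1 at -0.42 and Ppp1r14a at -0.40), with a mean of -0.19, camera adjusted p = 0.0123 and all 6 treated rats below all controls; adjusted p = 0.23 with an estimated correlation. Oxidative phosphorylation fell in 1 of 18 members, Atp5po (-0.27), and in 6 when adjusted over the list alone, with a mean of -0.17 and camera adjusted p = 4.2e-06; adjusted p = 0.158 with an estimated correlation. Glycolysis and hypoxia fell in 3 of 25 (Aldoc, Slc2a4 at -0.47 and Pfkm at -0.30; camera adjusted p = 0.042) and ribosomal proteins in 2 of 37 (mean -0.067, camera adjusted p = 0.00119), each with adjusted p = 0.367 with an estimated correlation. Median centring turned the ribosomal mean to 0.028 and kept 5 of the 13 list calls of this comparison. Fibroblast markers fell in 1 of 5, Dpep1 (-0.37; camera adjusted p = 0.035), and fatty acid oxidation genes in none of 28 singly (mean -0.13, camera adjusted p = 0.022); with an estimated correlation these gave adjusted p = 0.165 and 0.45. Striated muscle markers fell in 1 of 13, Ckm (-1.01), with a mean of -0.41 and camera adjusted p = 0.00119; adjusted p = 0.325 with an estimated correlation. Without WKY controls 5 and 6 that list's mean was -0.044, Ckm (-0.39) did not pass, 470 genes were called and 9 of the 13 list calls were kept; the fatty acid oxidation, glycolysis and leukocyte lists were lost as well.

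Nifedipine in SHR rats lowered cholesterol synthesis genes, with Idi1 changed by -0.78 (SE 0.09, adjusted p = 6.7e-06), Sqle by -0.69 (SE 0.10) and Cyp51 by -0.68 (SE 0.11), each with all 6 treated rats below all 6 controls. Fibronectin (Fn1), already lower in SHR, changed by a further -0.67 (SE 0.08, adjusted p = 1.5e-05). Penk changed by -0.94 (SE 0.11), and Pln, the inhibitor of the calcium pump, by -0.56 (SE 0.08). Selenbp1 rose by 0.81 (SE 0.08, adjusted p = 1.2e-07) and Lbp, which binds bacterial lipopolysaccharide, by 0.97 (SE 0.13). limma called 457 genes changed, 307 higher and 150 lower (86 and 20 with median centring, 1119 and 1182 with array weights); 40 differed by at least 1.5-fold and 2477 had an unadjusted p under 0.05. No overlap was seen in 260 genes, 1.34% where chance gives 0.216%. Of 100 splits of these rats, the real one included, 6 gave 457 genes or more, so chance is not excluded for this count. The count depended on single animals: 770 genes without SHR control 1, 863 without SHR nifedipine 1, 293 without SHR control 3, 271 without SHR control 4, 299 without SHR nifedipine 6 and 690 without the 3 animals of widest spread. It also moved with the fit, from 106 with median centring, 132 from the authors' value table and 142 with only the 2 groups to 1021 on all 58 arrays and 2301 with array weights.

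Other rises without overlap were Spon1 (0.82), Podxl (0.69), the growth factor binding protein Igfbp3 (0.68), Sult1a1 (0.61), Gstm7 (0.59), the small heat shock protein Cryab (0.55), Srsf5 (0.45) and Zfp386 (0.41). Igf2 (0.49) and Fgf7 (0.31) rose too. Other falls were Rgs4 (-0.98), which limits receptor signalling, Cpe (-0.72), a peptide-processing enzyme, the glutaminase Gls2 (-0.70) and Mfge8 (-0.63). Atp2a2 rose (0.24), and Trpc4 (-0.38), Rcan1 (-0.16), Ramp1 (-0.36) and Avpr1a (-0.17) fell. Among the fixed genes Ace, Agtr1a and Cd36 moved by 0.08, -0.01 and 0.07, and Spp1 by -0.50, none passing.

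Of 15 cholesterol synthesis genes 7 fell and none rose (8 fell when adjusted over the list alone), with Msmo1 (-0.52), Fdps (-0.49), Hmgcs1 (-0.39) and Sc5d (-0.23) beside the 3 named first. The list mean was -0.28, camera adjusted p = 7.3e-12 and adjusted p = 0.027 with an estimated correlation; all 6 treated rats had a list mean below all controls. Ribosomal proteins rose in 5 of 37 and fell in none (12 when adjusted over the list alone), for example Rps6 (0.22), Rpl24 (0.23), Rpl5 (0.20) and Rpl19 (0.19), with a mean of 0.13 and camera adjusted p = 4.6e-13; adjusted p = 0.119 with an estimated correlation. Proteoglycans and matricellular proteins fell in 5 of 22 and rose in 1 (6 and 1 over the list alone), with Sparcl1 (-0.40) and Sdc1 (-0.37) lower and Spon1 higher; the mean was -0.096, camera adjusted p = 0.0246, and adjusted p = 0.062 with an estimated correlation. Adipocyte markers (mean 0.28) and fatty acid oxidation genes (mean 0.18) rose as lists with no member passing alone, at camera adjusted p = 0.00341 and 0.00024, in 3 of 6 treated rats each above all controls; adjusted p = 0.525 and 0.487 with an estimated correlation. Without SHR nifedipine 3 their means were 0.14 and 0.10 (adjusted p = 0.15 and 0.051), and without SHR control 1 they were 0.16 and 0.12 (adjusted p = 0.073 and 0.018). Leaving out SHR nifedipine 3 or SHR control 1 kept 3 of the 6 list calls each, cholesterol synthesis and ribosomal proteins in both cases. Leaving out SHR control 5 also kept 3, and leaving out SHR control 6 or SHR nifedipine 1 kept 4 each. Candidate genes of the SHR strain rose (mean 0.10, camera adjusted p = 0.029), with Spon1 the only member to pass; adjusted p = 0.141 with an estimated correlation.

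After 3 weeks of washout no gene passed the test against untreated SHR rats: limma called 0 of 19447 genes, in 5 washout and 6 control rats, with a lowest adjusted p of 0.13. Fn1 (0.04, SE 0.09), Spp1 (0.11) and Cd36 (0.03) lay at the control level. At an unadjusted p under 0.05 there were 2151 genes, and 155 genes showed no overlap, 0.797% where chance gives 0.433%. Array weights called 378 genes and the fit on all 58 arrays 62, while 0 were called without any single animal. Among genes with a symbol the smallest p values belonged to Zfp386 (0.40), Srsf5 (0.35), the fatty acid oxidation gene Cpt1a (0.35), H1f0 (0.33) and Sphk1 (0.33), with adjusted p of 0.13 to 0.202. As lists, fatty acid oxidation genes (mean 0.22, camera adjusted p = 4.6e-06), adipocyte markers (0.34, 0.000134), circadian genes (0.19, 0.00473) and glycolysis genes (0.10, 0.00239) were higher, and ribosomal proteins were lower (-0.058, 0.00473). With an estimated correlation none of these lists passed: adjusted p = 0.442 for fatty acid oxidation, circadian and glycolysis genes, 0.605 for adipocyte markers and 0.803 for ribosomal proteins. In each of the higher lists all 5 washout rats lay above the control mean but at most 3 above all controls, and 0 for circadian genes. In each of the lists that were higher, SHR control 1 had the lowest mean of the controls. Without it 2 of the 5 calls were kept, with means of 0.22 for adipocyte markers and 0.16 for fatty acid oxidation genes, while glycolysis (0.064), circadian (0.14) and ribosomal genes (-0.045) no longer passed (adjusted p = 0.067, 0.067 and 0.069). Without the 3 animals of widest spread 1 call was kept, fatty acid oxidation (0.13). With array weights 0 of the 5 calls were kept. Median centring turned the ribosomal mean to 0.067.

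Set against the nifedipine rats, the washout rats differed in many of the genes called with nifedipine, with the sign turned. The washout rats were studied 3 weeks later in the protocol, and the authors' value table scales their arrays to another spread. Withdrawal of the drug therefore cannot be told apart from time or from a difference in array handling. Penk rose by 1.01 (SE 0.11, adjusted p = 3.4e-06), Cpe by 0.92 (SE 0.09), Gls2 by 0.82 (SE 0.07) and Fn1 by 0.70 (SE 0.09). Selenbp1 changed by -0.94 (SE 0.08, adjusted p = 2.3e-08), Lbp by -0.99 (SE 0.14) and Spon1 by -0.85 (SE 0.14). In each of these the 5 and 6 rats did not overlap. limma called 373 genes changed, 191 higher and 182 lower, but 306 and 502 without the 3 animals of widest spread, 357 and 493 with array weights and 187 and 288 without SHR nifedipine 1; 48 differed by at least 1.5-fold, and 2428 had an unadjusted p under 0.05. No overlap was seen in 464 genes, 2.39% where chance gives 0.433%. Without the 3 animals of widest spread 808 genes were called; the fit moved the count from 78 with median centring and 172 with only the 2 groups to 797 on all 58 arrays and 850 with array weights.

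Mfge8 (0.77), Ltbp2 (0.74), the ATP-gated channel P2rx1 (0.59), Sqle (0.59), Alpl (0.58) and Idi1 (0.57) rose, and Igfbp3 (-0.85), Cryab (-0.76), Gstm7 (-0.66), Igf2 (-0.66), Podxl (-0.63), Gucy1a1 (-0.57) and Aldoc (-0.49) fell. Pln (0.42), Trpc4 (0.45), Sdc1 (0.46), Sparc (0.41), Stmn1 (0.49) and the chaperone Hspa5 (0.48) rose as well. Cholesterol synthesis genes rose in 5 of 15 and fell in none (8 when adjusted over the list alone), including Fdps (0.50) and Cyp51 (0.47), with a mean of 0.24, camera adjusted p = 8e-11 and all 5 washout rats above all nifedipine rats; adjusted p = 0.021 with an estimated correlation. Ribosomal proteins fell in 9 of 37 and rose in none (29 when adjusted over the list alone), including Rpl24 (-0.29), Rps7 (-0.27), Rps6 (-0.24) and Rpl27 (-0.23), with a mean of -0.18, camera adjusted p = 1.6e-23 and all 5 rats below all nifedipine rats; adjusted p = 0.021 with an estimated correlation. Oxidative phosphorylation (mean 0.11, camera adjusted p = 0.00307), proliferation (0.12, 0.015) and glycolysis (0.074, 0.047) were higher and endothelial markers lower (-0.16, 0.049), with Cd93 (-0.33) the only member of that last list to pass. With an estimated correlation these gave adjusted p = 0.475, 0.175, 0.475 and 0.322.

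**Figure D2:**
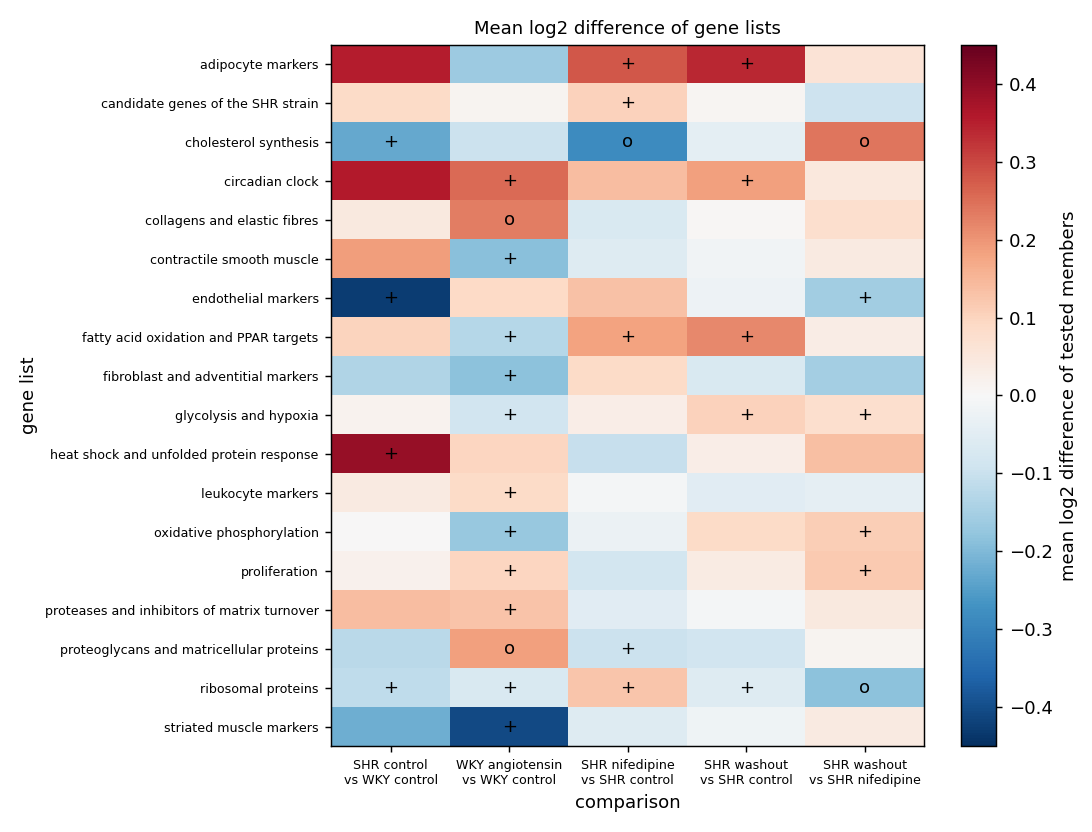
Mean log2 difference of the gene lists called by camera in at least 1 comparison, with + where a list was called with the preset correlation only and o where it was also called with an estimated correlation.

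Of the 457 genes called with nifedipine, a count for which chance is not excluded, 207 also changed between washout and nifedipine. All of these went in the opposite direction, among them Fn1, Penk, Cpe, Selenbp1 and Idi1. Independent lists would share 1.47 and 2.87 genes of opposite sign where 99 and 108 were seen. These 2 comparisons share the nifedipine rats, which alone favours opposite signs: their correlation over genes was -0.56, against a mean of -0.43 and a range of -0.94 to 0.35 in simulated data with no effect, and -0.20 (-0.54 to 0.14) with those rats split. Of the 6 lists called with nifedipine, cholesterol synthesis and ribosomal proteins were called with the opposite sign from nifedipine to washout and the others were not called: adipocyte markers (0.062), fatty acid oxidation (0.035), proteoglycans (0.011) and candidate genes of the SHR strain (-0.095). Of the 457 genes, 271 also differed between the strains, and 226 of these moved against the strain difference (176 rose with the drug and were lower in SHR, and 50 fell with it and were higher in SHR). The nifedipine and strain comparisons share the SHR controls: the correlation over genes was -0.38 against -0.72 in simulated data (-0.96 to -0.14), the covariance -0.0103 against -0.00736, and -0.14 (-0.30 to 0.16) with the controls split. The nifedipine and washout effects correlated at 0.52 against 0.56 simulated (-0.51 to 0.93) and 0.040 (-0.24 to 0.27) with the controls split. Angiotensin and strain effects share the WKY controls and correlated at 0.26 against 0.30 simulated (-0.19 to 0.81) and 0.21 (0.047 to 0.31) with the controls split, with a covariance of 0.00744 against 0.00144 simulated; every split gave a value above 0. Both comparisons called 386 genes: 89 higher in both, such as Dbp, 217 lower in both, such as Rgs5 and Selenbp1, and 76 higher with angiotensin but lower in SHR, such as Fn1, with 4 the other way, where independent lists would share 53.6, 44.2, 54.7 and 43.4. The washout minus nifedipine difference, which shares no animal with the strain difference, correlated with it at 0.078, inside the range of -0.66 to 0.76 in simulated data. Of 194 genes called in both, 51 were higher and 103 lower in both, and 31 and 9 had opposite signs, where independent lists would share 29.2, 28.4, 29.8 and 27.8; these counts were not set against relabelings.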

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

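The tests on striated muscle markers, on fat of any kind, without the 3 animals of widest spread, with the adipocyte covariate, on the correlation of washout minus nifedipine with the strain difference and on the genes that angiotensin and nifedipine move oppositely were chosen after the results were seen; the other tests were worded beforehand, though the wording of every test was stored only after they had run. Of 474 values tested, 44 had an animal further from its group than the limit for single animals, where 23.7 are expected by chance, and 20 of the 44 belong to SHR control 1. Dixon's ratio is given for each. SHR control 1 was low in Acadl (0.705), Atp5pf (0.746), Dnaja1 (0.669), Gsta1 (0.749), Gstm5 (0.655), Herpud1 (0.797), Hspa8 (0.739), Ifi27 (0.780), Msmo1 (0.762), Pcolce (0.873), Prps2 (0.720), Spon1 (0.712) and Spp1 (0.629), and in the list means of candidate genes of the SHR strain (0.656) and of heat shock genes (0.632). It was high in Cnn1 (0.732), Cx3cl1 (0.723), Egr1 (0.693), Jun (0.644) and Ramp1 (0.857). SHR control 5 was high in Atp2a2 (0.672) and H1f0 (0.700), and SHR control 6 was low in Fgf7 (0.887) and Tcea2 (0.823) and high in Selenbp1 (0.630) and Sparcl1 (0.712). SHR nifedipine 1 was low in Atp2a2 (0.768) and Spp1 (0.664) and high in Cdk1 (0.735) and the spread over probes (0.775), and SHR nifedipine 6 was high in Msmo1 (0.711). WKY angiotensin 1 was low in Atp2a2 (0.785), WKY angiotensin 5 high in Pnoc (0.653) and low in Ppp1r1a (0.863), and WKY angiotensin 6 low in Actg2 (0.761), Fn1 (0.651), Pln (0.838) and Timp2 (0.680). WKY control 1 was low in Cd3d (0.706), WKY control 3 high in Avpr1a (0.741), and WKY control 5 high in Cdk1 (0.708), Pnoc (0.692), Serpinh1 (0.763) and Spp1 (0.725).

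Whether chance alone could give these counts was tested by splitting the animals of the 2 groups in 100 ways, the real split included. Chance can be excluded for the strain count (6001 genes, highest other split 3943; 1 of 100 splits, the real one, reached it), the angiotensin count (635 against 229; 1 of 100) and the washout against nifedipine count (373 against 63; 1 of 100). Chance cannot be excluded for the nifedipine count: 6 of 100 splits gave 457 genes or more, the highest other split 3636. The 0 genes of washout against control are reached by all 100 splits, the highest being 847. For the number of lists called, chance can be excluded for angiotensin (13 against a highest other of 10; 1 of 100 splits) in the fit used here only, since 10 lists or fewer were called without WKY angiotensin 6 (10), with the adipocyte covariate (10), without WKY controls 5 and 6 (9), with the strict filter on dim probes (10), on Cy5 arrays (8), with median centring (6) and with an estimated correlation (2), where no splits were run. It cannot be excluded for strain (4, highest 11; 40 of 100 splits), nifedipine (6, highest 10; 26 of 100), washout against control (5, highest 10; 27 of 100) or washout against nifedipine (6, highest 10; 19 of 100). The correlation of washout minus nifedipine with the strain difference was 0.078, and 92 of 100 relabelings were as large, the highest other being 0.517.

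Striated muscle markers were lower than in WKY controls after angiotensin and, for single genes, in SHR. Of 13 tested members, 12 had their 2 highest WKY control values in WKY controls 5 and 6. As these rats were picked because the markers were high in them, this is no test, and striated muscle carried over in those samples stays open. An effect of angiotensin on these genes cannot be told apart from no effect: 4 of the WKY controls had a list mean inside the range of the angiotensin rats, although a small fall is not excluded. Without WKY controls 5 and 6, a choice made on this very list, its mean was -0.044.

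Ucp1 was higher in SHR controls. Whether more adherent fat of any kind in the SHR samples is the whole cause stays undecided. Within animals, Ucp1 minus the mean of Adipoq and Fabp4 was higher in SHR, with a lower 95% bound of 1.61. Both markers were picked after they were seen not to differ between the strains (-0.15 and 0.05), so this outcome was fixed beforehand. Of other fat genes, Thrsp (1.12), Fasn (1.09) and Cpt1b (1.17) rose with Ucp1, while Plin1 (0.04) and Adrb3 (0.13) did not pass. The upper bound of Lpl was 1.30. RNA of adipocytes as the source of the Ucp1 signal fits, since over the 17 SHR rats, centred within groups, Ucp1 followed Adipoq with a Pearson r of 0.967 (permutation p = 2e-05), a Spearman rho of 0.953 (permutation p = 4e-05) and 0.942 without the 2 farthest rats. The correlation was 0.973, 0.966 and 0.965 within controls, nifedipine and washout. Browner fat in SHR, or fat taken from another site along the aorta, may lie behind the strain difference and stays untested.

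Cholesterol synthesis genes were lower with nifedipine, and higher in washout rats than in nifedipine rats. For that second difference, withdrawal cannot be told apart from time or array handling. The 3 animals of widest spread are not the source, as the list mean without them was -0.33. Adipocyte content of the samples is not the source either, as the mean with the adipocyte markers as a covariate was -0.30, and camera called the list in both. In either setting 2 of 6 nifedipine list calls were kept, cholesterol synthesis and ribosomal proteins, and with the covariate 2 of 5 for washout against control, but the covariate removes the adipocyte list by construction and its loss says nothing. An effect of nifedipine on sterol synthesis in the media is a hypothesis, found and tested on the same data, and food intake, signals from the liver and the time of tissue collection stay open and untested.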

How the results depend on the processing

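The fits without 3 or 2 chosen animals and with the adipocyte covariate were chosen after the results were seen. Over all alternatives 6613 of 7344 values of named genes kept their direction and side of the threshold, 715 lost the threshold, 16 gained it and 0 reversed. For lists 1681 of 1843 kept both, 119 lost, 41 gained and 2 reversed. These tallies include scaling between arrays, which keeps all 246 gene and 64 list values by construction. Each probe alone reuses the same probe values and kept all 246 gene values. Named genes were mostly picked for passing, so these shares do not stand for all genes. The strain count was 6001, from 4295 with median centring to 7817 with array weights, and 533 with a fold of at least 1.5 as well, which asks for more by construction. The angiotensin count of 635 became 277 with median centring, 2068 with only the 2 groups compared, 2180 with array weights, 1215 on 58 arrays with the animal as a random block, 1803 with the authors' value table and 70 with the fold. The nifedipine count of 457 became 284 with the Feature Extraction log ratio, 106 with median centring, 241 and 281 with Cy5 or Cy3 arrays alone, 142 with only the 2 groups, 2301 with array weights, 1021 on 58 arrays, 132 with the authors' table, 40 with the fold and 690 without the 3 animals of widest spread. Leaving out 1 animal gave 271 to 863. Washout against control, 0 genes, became 378 with array weights and 62 on 58 arrays, and stayed 0 whichever animal was left out. Washout against nifedipine, 373 genes, became 78 with median centring, 172 with only the 2 groups, 850 with array weights, 797 on 58 arrays, 48 with the fold and 808 without the 3 animals; leaving out 1 animal gave 277 to 475. Leaving out 1 animal gave 4441 to 6638 for strain and 427 to 687 for angiotensin. With an estimated correlation the lists called fell to 0 of 4 for strain, 2 of 13 for angiotensin, 1 of 6 for nifedipine, 0 of 5 for washout against control and 2 of 6 for washout against nifedipine. Ribosomal proteins reversed with median centring, to 0.028 with angiotensin and 0.067 for washout against control, losing the call in both (adjusted p = 0.448 and 0.209). The correlation of nifedipine and washout effects, 0.52, became 0.040 with the shared controls split, by the construction of that alternative. The 2 groups fitted alone carry their own spread in place of a spread shared over all 5, and single dyes leave 1 array per rat; for the other changes the cause was not tested. With the replicate number as a block the counts were 6109, 708, 520, 0 and 402 in the order above. In no pair of groups did every pair of rats with the same number correlate above 0.1, and the numbers are not read as pairing. SHR controls and nifedipine rats of the same number nevertheless correlated at a mean of 0.25, against -0.025 for other numbers. For SHR controls and washout rats these means were 0.18 and -0.035. In the other pairs of groups the same-number mean was at most 0.067. A structure shared by number among SHR rats is therefore not excluded. At least 79.4% of the probes were well above background on every array. The lowest shares were on the Cy5 arrays of SHR nifedipine 1 (79.4%) and SHR control 1 (82.7%), both among the rats of widest spread. Whether weak signal adds to their spread was not tested. The offset of 50 compresses rises and falls, most of all for dim genes.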

Other observations

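Genes changed by both angiotensin in WKY and nifedipine in SHR, which share no animals, were examined after it was seen that they tend to differ in sign. Of 88 genes called in both, 72 went in opposite directions: 35 rose with angiotensin and fell with nifedipine, and 37 did the reverse, where independent lists would share 2.71 and 4.48. Of 100 splits of the 12 SHR rats only the real one reached 72, and the highest other split gave 32. The pattern was picked on these same data and the angiotensin calls were held fixed in the splits, so chance is not excluded by this count. Among the opposite genes 25 have a symbol, and 5 of the 16 of like sign do. Fn1 (1.03 with angiotensin, -0.67 with nifedipine), Penk (0.95, -0.94), Cpe (0.52, -0.72) and Pln (0.38, -0.56) rose and fell, and Selenbp1 (-0.73, 0.81), Sult1a1 (-0.78, 0.61), Gstm7 (-0.33, 0.59), Aldoc (-0.64, 0.40) and Atp2a2 (-0.38, 0.24) fell and rose. Cdkn1b (0.62, 0.37), Lbp (0.52, 0.97), Hmgcs1 (-0.44, -0.39), Sdc1 (-0.24, -0.37) and Avpr1a (-0.32, -0.17) moved alike. Over all genes the correlation of both effects was -0.22, which lies inside the range of -0.52 to 0.45 in simulated data with no effect (mean -0.019) and adds nothing to the count. Opposite effects of raised and lowered pressure on the same genes are a possible explanation of these 72 genes, and direct actions of angiotensin and of the calcium channel blocker are another. The arrays cannot separate them, since pressure was not analysed here.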
